A study of Mus musculus with 12 samples.

How the data were processed

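The 12 libraries were bulk RNA-seq of mouse monocytes described as Ly6C+, Ly6C being a surface protein of classical monocytes. Per the labels' protocols, RNA was taken from sorted cells with a NucleoSpin RNA XS kit, libraries were made with a SMARTer Ultra Low RNA kit, which does not mark the strand of the transcript, and sequencing was on a NovaSeq X Plus. The groups followed the sample titles, with 3 libraries in each of 4 groups: bone marrow (BM), fetal liver KO, fetal liver Mixed and fetal liver WT. The genotype label was KO for the KO libraries and WT for the other 9. The embryonic day in the labels was 13.5 for the 3 KO libraries and for WT 1, and 15.5 for WT 2, WT 3 and the 3 Mixed libraries, and the bone marrow libraries carried no age. What "Mixed" means, which allele the KO libraries carry and which surface markers beyond Ly6C were used for sorting are not given in the sources used here. The series title names cMaf and Zeb2, and its design text names a mouse line called Z165KO and tissue macrophages, which are not the cells the sample labels name.

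The values used were estimated counts per gene, deposited by the authors in a single table of the series. Per the submitters' processing notes, DRAGEN, STAR, Subread, featureCounts and Salmon were run and the genome build was mm10, with no role or order of the tools stated. Of the nonzero deposited counts, 28.5% were not whole numbers (tolerance 1e-06), so an estimate that divides reads between overlapping or similar transcripts was part of the authors' processing. The deposited CPM and TPM tables were not used here. Counting was not stated to use strand, so genes with antisense partners are uncertain, as are gene families with near-identical members. The table had 55774 entries. Of these, 287 repeated an Ensembl gene with identical values under another Entrez number and were removed, which left 55487 genes, 234 of them sharing a symbol with another gene and kept under their own identifiers. Values were rounded to whole numbers.

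Total counts per library ran from 17384956 to 24473502. Genes were kept by edgeR's filterByExpr with the groups as classes (minimum count 10, minimum total count 15), which left 14618 genes for testing and removed 40869. The kept genes held at least 99.8% of the counts of each library. Scaling was by TMM, dispersions by estimateDisp (common biological coefficient of variation 0.0917), and each comparison was edgeR's quasi-likelihood test (glmQLFit with robust = TRUE, glmQLFTest) from 1 fit to all 12 libraries with a mean per group, so that the groups shared an estimate of the spread. P-values were two-sided and adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called higher or lower. Levels are counts per 1e+06 counts (CPM) on the TMM-scaled library sizes, given as mean ± SD of 3 libraries, and log-scale plots used a prior count of 2. The labels do not say that the 3 libraries of a group came from separate animals or litters, so p-values measure only the spread between these samples, which may be technical. Where a group had 1 to 3 counts in all, the ratio of counts is given with a 95% exact interval. Where all its libraries had 0 counts, a lower bound of the fold is given, computed from a floor of 3 counts per library. These intervals and floors cover counting error only. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the data.table package (1.17.8). Gene positions are 1-based and from the GENCODE annotation of GRCm38, the assembly that mm10 denotes.

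Tests, alternatives, 33 gene lists from textbook knowledge and the rule for naming genes were written before the data were examined. The rule named, for each comparison, Zeb2 and Maf, then among called genes with an average of at least 3 log2 CPM and all libraries of 1 group above all of the other the 8 with the largest and the 8 with the smallest log2 fold change, leaving out predicted genes and pseudogenes. For each list it named up to 4 called members with the largest change and an average of at least 1 log2 CPM or, where none was called, up to 2 members of highest level. Some genes that the rule names are not reported here. Other genes are said to have been chosen after their values were seen. Lists with at least 3 measured members were tested with limma's camera, which compares a list with all other genes, at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The same test was run with the correlation estimated from the data. The members higher and lower were counted with the adjustment over all genes and adjusted over the list alone. A further set, 200 genes per direction with the smallest p between bone marrow and Mixed and a change of over 2-fold, was tested in the comparison of KO with WT, which shares no library with it.

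The fit was tested on simulated data drawn from the real means and library sizes with 200 changed genes. In the simulated KO and WT comparison, over 14192 genes, 86.5% of the changed genes were recovered (62% at 1.5-fold, 88% at 2-fold, 96% at 4-fold and 100% at 8-fold) and 6.99% of the calls were false. A raised list was found, and 0 of 100 unchanged lists were called. Genes were drawn independently of each other, so false calls of lists with correlated members were not tested. Few genes were changed, so scaling under a broad change was not tested either. Libraries of a group were compared for repeats: all pairs differed by more than sampling noise, with chi-square per degree of freedom from 4.36 to 10.3. The alternatives were other scalings, DESeq2, other filters, a 1.5-fold threshold, removal of globin genes, fits to the 2 groups alone, the replicate number as a block, other uses of the age label, and leaving out each library.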

Results

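Gene expression was measured in Ly6C+ monocytes sorted from mouse bone marrow and fetal liver, in 4 groups of 3 libraries: bone marrow WT, fetal liver KO, fetal liver Mixed and fetal liver WT. Monocytes are blood phagocytes, and the fetal liver is the main blood-forming organ of the embryo before the bone marrow takes over. The series title sets the question as how cMaf, a transcription factor encoded by Maf, relates to expression of Zeb2, a zinc-finger repressor. Total counts per library were 18208917 to 21911312 in bone marrow, 20154514 to 24473502 in KO, 20332261 to 21542312 in Mixed and 17384956 to 21704037 in WT. Between 19649 and 21046 genes had a count in each fetal liver library, and 24422, 20077 and 19896 in the bone marrow libraries. Mitochondrial transcripts made up 0.976 to 1.03% of the counts in bone marrow, 1.98 to 2.2% in KO, 1.6 to 1.77% in Mixed and 2.02 to 2.23% in WT.

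By correlation, bone marrow, KO and Mixed libraries lay closest to their own group. WT libraries did so only in part: WT 2 correlated at 0.9851 with WT 3 and at 0.9868 with Mixed 2. Across genes, log CPM correlated at 0.9843 to 0.9885 within groups (genes are not independent replicates), at 0.9813 to 0.9868 between WT and Mixed, at 0.9534 to 0.9563 between KO and WT, and at 0.9105 to 0.9162 between bone marrow and WT. The first principal component (55.8% of the variance) set bone marrow apart, and the second (22.5%) set KO apart from the other fetal liver libraries. Sex-linked transcripts varied within KO and WT and were alike within Mixed and within bone marrow, so in comparisons with bone marrow they went with the tissue. The Y-linked Ddx3y was at 51.6 and 41.9 CPM in KO 1 and KO 2 and had no count in KO 3 (floor 0.123 CPM). It was at 36.5 to 39.1 CPM in the Mixed libraries, at 19.7, 20.4 and 45.8 CPM in WT, and had no count in the bone marrow libraries. Xist, transcribed from the inactive X chromosome, was at 25.7, 28.7 and 83.1 CPM in KO, 92, 97.7 and 25.3 CPM in WT, 46.7 to 57.3 CPM in Mixed and 113, 110 and 134 CPM in bone marrow.

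**Figure D1:**
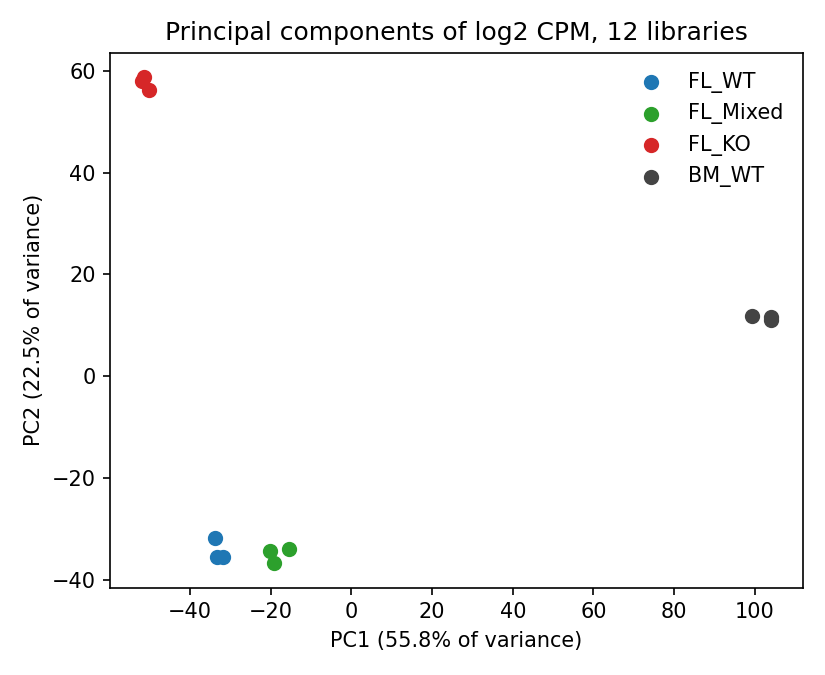
Scores of the 12 libraries on the first and second principal components of log2 CPM, each point a library coloured by group. Bone marrow libraries lay at 99.2 to 104 on the first component, and KO libraries lay at 56.3 to 58.7 on the second, where WT and Mixed libraries lay between -36.7 and -31.7.

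Zeb2 was low in every KO library. Its level was 23.8, 20.1 and 22.5 CPM in the KO libraries, against 149.7 ± 13.1 CPM in WT (lowest library 141), 167.4 ± 10.4 in Mixed (lowest 159) and 323 ± 13.8 in bone marrow (lowest 311). Against WT it fell by 2.75 on the log2 scale in KO (SE 0.0771, 6.75-fold, adjusted p = 3.95e-17), and against WT it was 2.16-fold higher in bone marrow (log2 1.11, SE 0.0685, adjusted p = 4.68e-12). Zeb2 (ENSMUSG00000026872) is on the minus strand of chromosome 2, from 44983632 to 45117395, and an antisense gene, Zeb2os, lies within it at 45110707 to 45114087, so part of its counts is uncertain in libraries without strand. The Z165 line is known as a deletion of an enhancer upstream of Zeb2 that leaves its exons in place. Whether the KO libraries carry it is not given. If they do, their Zeb2 level is a readout of expression and no direct check of a deletion. Maf (ENSMUSG00000055435, minus strand of chromosome 8, 115682942 to 115707794) was at 9.99 ± 2.44 CPM in KO, 13.7 ± 1.43 in WT, 9.16 ± 1.52 in Mixed and 3.28 ± 0.882 in bone marrow (SD, n = 3). Maf was 4.17-fold lower in bone marrow than in WT (adjusted p = 1.18e-08). Its differences from WT in KO (log2 -0.45, SE 0.179, adjusted p = 0.0549) and in Mixed (log2 -0.57, SE 0.18, adjusted p = 0.0539) did not pass the threshold. The call changed with the processing: 6 of 24 alternatives called Maf in KO, with adjusted p from 0.00884 to 1, and 10 of 23 called it in Mixed, from 0.00893 to 1.

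The comparison of KO with WT gave a broad change, with 5565 of 14618 genes called, 2654 higher and 2911 lower in KO. At 2-fold or more, 932 genes were higher and 557 lower. Among called genes averaging at least 3 log2 CPM with groups that did not overlap, the largest rises were in Ms4a1, which encodes a B cell surface protein (75.1 ± 4.53 CPM in KO, 0.106 ± 0.112 in WT, adjusted p = 8.57e-13, chromosome 19, 11249675 to 11266241), and Gcsam (72.4 ± 12.1 and 0.0946 CPM). Clec9a, a receptor for dead cells on cross-presenting dendritic cells (chromosome 6, 129408862 to 129424763), had 1328 counts in KO and 3 in WT, a ratio of 422 (95% interval 144 to 2050). Cdh17 (28.4 ± 5.14 and 0.154 CPM), Rab30 (87.4-fold), P2ry10 (71.6-fold) and Ciita (65.8-fold) followed. Within the same limits, the genes that fell most were Gpsm2 (19-fold), the adhesion receptor Adgre4 (15.2-fold, 3.26 ± 1.74 CPM in KO and 50.4 ± 5.8 in WT), Cd302 (11.6-fold), Ednrb (8.69-fold), Trem2 (7.72-fold), Zeb2, Ldhb (6.31-fold) and F13a1. F13a1, the A chain of coagulation factor XIII (chromosome 13, 36867178 to 37050244), was at 390.0 ± 44.7 CPM in KO and 2421 ± 215 in WT (log2 -2.63, SE 0.0724, adjusted p = 2.19e-15). The naming rule itself required all 3 KO libraries of these genes to lie on 1 side of all 3 WT libraries.

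**Figure D2:**
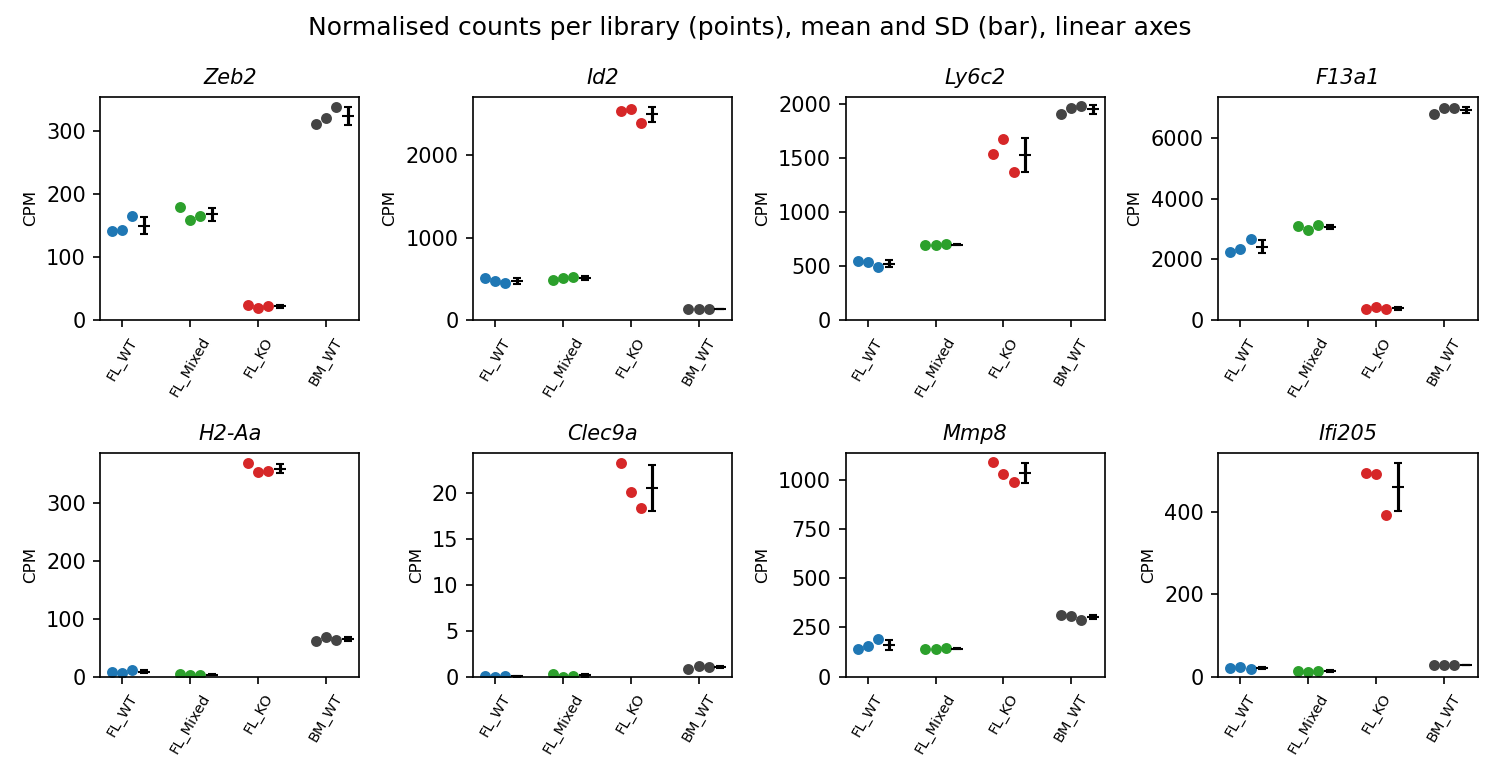
Levels of 8 genes in CPM on linear axes, each point a library and each bar the mean with its SD, for 3 libraries in each of the 4 groups. Zeb2 averaged 22.2 CPM in KO and 149.7 in WT, Id2 2485 and 474.8, and H2-Aa 358.8 and 8.8.

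Antigen presentation genes were higher in KO. All 12 measured members of the MHC class II list were higher, among them H2-Aa (358.8 ± 7.69 CPM in KO, 8.8 ± 2.11 in WT, 40.7-fold), H2-Ab1 (38-fold), H2-Ob (45.4-fold) and Ciita, the master activator of these genes (39.8 ± 2.17 and 0.587 ± 0.306 CPM). The list passed camera (adjusted p = 3.16e-11), with adjusted p = 0.0915 with an estimated correlation. Of 16 members of the MHC class I list, 11 were higher and 0 lower, including the peptide transporters Tap2 (4.03-fold) and Tap1 (3.75-fold), the immunoproteasome subunit Psmb9 (3.14-fold) and Nlrc5 (4.67-fold). That list had adjusted p = 3.21e-06, and adjusted p = 0.168 with an estimated correlation. The conventional dendritic cell list was the single list that kept its call with an estimated correlation (adjusted p = 3.21e-06, and adjusted p = 0.0222 with an estimated correlation). Its 14 members split into 11 higher, such as Clec9a, Dpp4 (79.8 ± 1.52 and 3.1 ± 0.508 CPM, 25.8-fold) and Itgax, which encodes CD11c (13.9-fold), and 3 lower. Cd209a (0.225 and 8.52 CPM, 33.9-fold) was lower under the naming rule, and Clec10a (0.0468 and 2.12 CPM) and Irf4 (0.576 and 1.34 CPM) were named after their values were seen. Of 8 members of the plasmacytoid dendritic cell list, 3 were higher and 1 lower, with Lair1 6.22-fold higher and Runx2 2.09-fold lower (adjusted p = 0.145).

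Interferon-induced genes rose together in KO. All 25 members of the type I interferon list were higher, with Ifi205 at 460.6 ± 58.5 CPM against 21.5 ± 2.07 in WT (21.4-fold), Oasl1 7.19-fold, Oas3 6.85-fold and Usp18 4.77-fold higher (adjusted p = 4.58e-19 for the list, and adjusted p = 0.0999 with an estimated correlation). Of 14 interferon gamma induced GTPases, 10 were higher and 1 lower, with Tgtp1 13-fold and Gbp4 2.93-fold higher (adjusted p = 1.03e-03, and adjusted p = 0.157 with an estimated correlation). The lower member was Gbp7, named after its value was seen. The Ifi200, Tgtp and Gbp genes have close copies, so single members are uncertain. The cytokine and NF-kB list was not called (adjusted p = 0.851), with 1 of 14 members higher and 3 lower. Ccl2, the chemokine that recruits monocytes through Ccr2, was 5.46-fold lower in KO.

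Neutrophil and B cell genes also differed, unevenly within each list. Of 20 neutrophil list members, 13 were higher and 1, Mcemp1, lower in KO (adjusted p = 3.21e-06, and adjusted p = 0.476 with an estimated correlation). Chil1 was at 528.1 ± 18.2 CPM against 15.8 ± 7.73 in WT, Mmp8, a collagenase of neutrophil granules, at 1033 ± 49.4 against 162.4 ± 24.8, Stfa2 was 12.2-fold and Ly6g 13.3-fold higher. Stfa2 lost its call with the age label as a covariate, a fit that sets KO against WT 1 alone, and the Stfa genes are near-identical copies. The secondary granule genes Ngp (239 ± 207 CPM in KO, 416 ± 252 in WT, adjusted p = 0.38), Ltf (adjusted p = 0.568) and Camp (adjusted p = 0.675) and the mature neutrophil gene Retnlg (16.7 ± 14.1 and 13.8 ± 7.7 CPM, adjusted p = 0.757) were not called. In the B cell list 5 of 10 members were higher (6 when adjusted over the list alone) and 1 lower (adjusted p = 0.0156, and adjusted p = 0.144 with an estimated correlation). Fcrla (65.9-fold), Cd22 (9.64-fold) and Ighm (338.7 ± 41.9 and 66 ± 9.68 CPM) were higher with Ms4a1, whereas Cd79a, which encodes a core part of the B cell receptor complex, averaged 0.347 CPM in KO. Cd79b was lower (61.7 ± 4.82 and 83.9 ± 4.16 CPM). Of 7 eosinophil list members 4 were higher and 0 lower (adjusted p = 0.055), with Siglecf 1.71-fold higher, a call lost with the age label as a covariate. The primary granule list had 5 higher and 6 lower of 14 (adjusted p = 0.672), with Prss57 5.15-fold and Nkg7 3.53-fold higher and Cst7 4.57-fold and Igfbp4 4.46-fold lower.

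Monocyte and macrophage genes moved in both directions. In the classical monocyte list 8 of 18 members were higher and 7 lower (8 higher and 8 lower when adjusted over the list alone), and the list was not called (adjusted p = 0.949). Ly6c2, which encodes the sorting marker, was at 1531 ± 156 CPM in KO and 525.6 ± 31.1 in WT (2.91-fold, uncertain because of close Ly6 copies), whereas F13a1, the proteoglycan Vcan (5.01-fold) and the lipopolysaccharide coreceptor Cd14 (3.03-fold) were lower. In the non-classical list 3 were higher and 7 lower of 16 (5 higher and 7 lower over the list alone, adjusted p = 0.323), with the scavenger receptor Cd36 32.5-fold higher and Cx3cr1, the fractalkine receptor, 4.08-fold lower. The tissue macrophage list fell: 0 of 23 members were higher and 6 lower, among them Trem2, Gpnmb (5.51-fold), Cx3cr1 and Nr1h3, which encodes the liver X receptor alpha (3.14-fold). Its camera adjusted p was 3.14e-03, and adjusted p = 0.512 with an estimated correlation. In KO set against Mixed the list was not called by camera (adjusted p = 0.217). Among 23 myeloid transcription factors 6 were higher and 9 lower (6 and 11 over the list alone, adjusted p = 0.71). Id2, which encodes an inhibitor of E proteins and marks dendritic cell commitment, was at 2485 ± 95.1 CPM against 474.8 ± 32.7 (log2 2.39, SE 0.0554, adjusted p = 1.79e-18, chromosome 12, 25093799 to 25097140). Cebpe was 3.42-fold higher and Cebpa 3.69-fold lower. The stem and progenitor list had 4 higher and 4 lower of 16 (6 and 6 over the list alone, adjusted p = 0.949), with the cytokine receptor Flt3 10.2-fold higher and Cd34 3.07-fold lower.

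**Figure D3:**
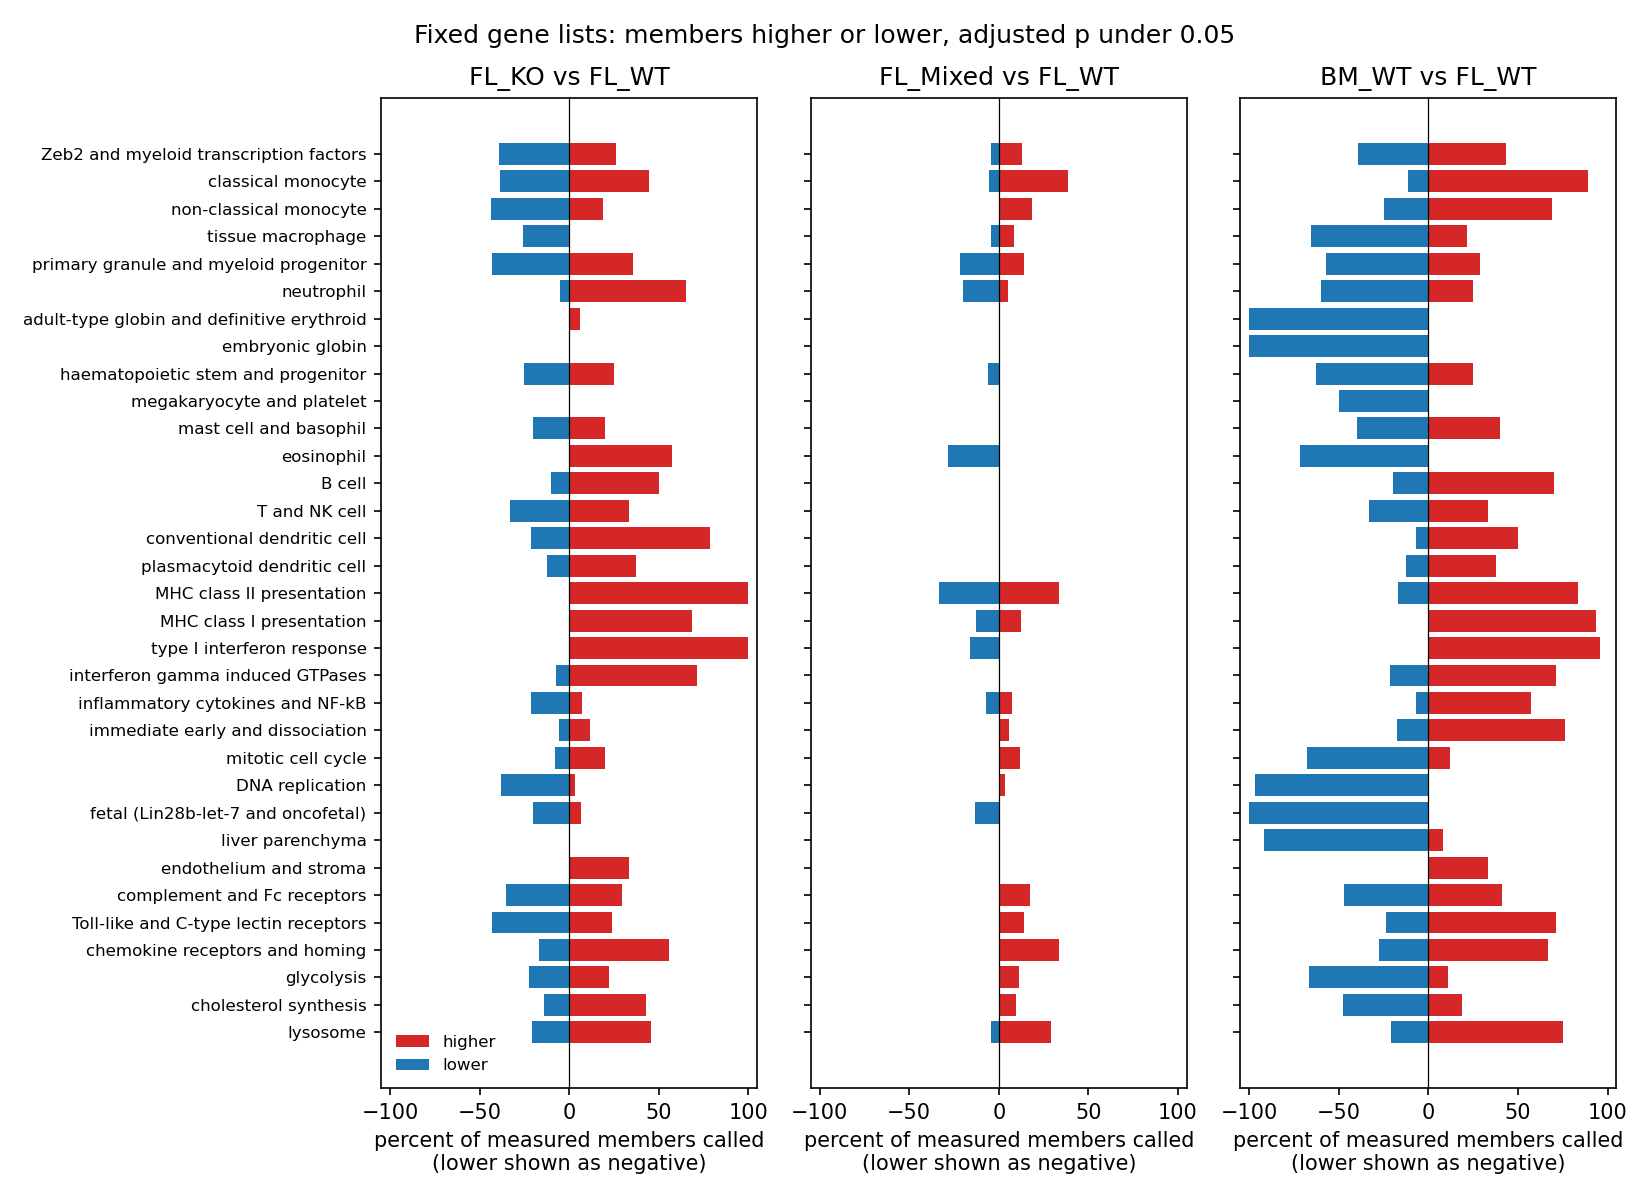
Percent of the measured members of each of the fixed gene lists that were called higher (to the right) or lower (to the left) than in WT, in KO, Mixed and bone marrow. All 12 MHC class II and all 25 type I interferon genes were higher in KO, and all 15 fetal genes were lower in bone marrow.

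Among the remaining lists, chemokine receptor and homing genes had 10 of 18 members higher and 3 lower in KO (adjusted p = 3.14e-03, and adjusted p = 0.157 with an estimated correlation), with Cxcr3 7.47-fold, Itgb7 5.37-fold and S1pr1 5.04-fold higher. Cholesterol synthesis genes had 9 of 21 higher and 3 lower, led by Srebf2, which encodes the transcription factor of the pathway (2.39-fold), and Fdps (2.08-fold), with adjusted p = 0.0302, and adjusted p = 0.168 with an estimated correlation. Lysosome genes had 11 of 24 higher and 5 lower (13 and 5 over the list alone), with Psap at 5680 ± 317 CPM against 2654 ± 155 and Cd63 1.82-fold lower. Their adjusted p was 0.0448, and adjusted p = 0.697 with an estimated correlation. Toll-like and C-type lectin receptors had 5 higher and 9 lower of 21 (adjusted p = 0.71), Tlr3 being 8.03-fold higher, and DNA replication genes 1 higher and 11 lower of 29 (adjusted p = 0.121). Mitotic genes had 5 of 25 higher and 2 lower (adjusted p = 0.0921) and glycolysis genes 4 and 4 of 18 (Hk3 3.31-fold lower, adjusted p = 0.967). The counts were for complement and Fc receptor genes 5 and 6 of 17 (adjusted p = 0.851), for immediate early and dissociation genes 2 and 1 of 17 (adjusted p = 0.851), and for fetal genes 1 and 3 of 15 (adjusted p = 0.925). Among markers of other cells, 1 of 17 erythroid genes was higher (Slc25a37, 1.56-fold). For embryonic globin 0 of 3, for megakaryocytes 0 of 8 and for liver parenchyma 0 of 12 genes were called. Mast cell and basophil genes had 1 of 5 higher (Mcpt8, 7.09-fold) and 1 lower (Gata2, 3.58-fold, not called without KO 2). Of 3 T and NK cell genes 1 was higher and 1 lower, and of 3 endothelial and stromal genes Pecam1 was higher (3.61-fold). The KO libraries and WT 1 carried the earlier embryonic day and the other WT libraries the later, so age and genotype overlapped in part. A fit with the age label as a covariate over the 9 fetal liver libraries sets KO against WT 1 alone. It rests on 1 WT library, so it cannot tell age from differences between single libraries.

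Mixed monocytes resembled WT monocytes, and their differences were small. Of 14618 genes 1180 were called, 615 higher and 565 lower in Mixed, and 14 and 52 of them by 2-fold or more. That count ran from 414 to 1457 over fits without 1 library, and a test against a 1.5-fold change called 0 genes. Among called genes averaging at least 3 log2 CPM with groups that did not overlap, the extracellular matrix gene Fn1 (chromosome 1, 71585520 to 71653200) was at 140.1 ± 3.18 CPM in Mixed and a mean of 74.7 in WT (log2 0.90, SE 0.124, adjusted p = 0.00231). Lilra6 (1.72-fold), Galnt9 (1.66-fold), Cd300lg (1.65-fold), Pira2 (1.63-fold), Adora2b (1.6-fold), Grk3 (1.58-fold, adjusted p = 1.08e-05) and Natd1 (1.58-fold) were the next higher within these limits, Pira2 and Lilra6 being members of a receptor family with close copies. Spp1, which encodes osteopontin (chromosome 5, 104435118 to 104441050), was at 6.69 ± 0.623 CPM in Mixed and 33 ± 18.8 in WT (4.95-fold lower, adjusted p = 0.00955). Chil1 was 3.92-fold, Dab2 3.18-fold, Cstdc5 2.47-fold, Slfn4 2.46-fold, Cd63 2.08-fold, Ms4a3 1.91-fold and Perp 1.78-fold lower. Without Mixed 1, Spp1, Chil1, Cstdc5 and Dab2 lost their calls (adjusted p = 0.058, 0.0702, 0.0736 and 0.147). Over the alternatives their adjusted p ran from 9.37e-09 to 0.555, 3.57e-07 to 0.636, 0.000419 to 0.983 and 0.000296 to 1. Chil1, Cstdc5 and Dab2 also lost theirs without Mixed 3, and Dab2 without Mixed 2, WT 1, BM 2 or BM 3. Zeb2 was not called (log2 0.16, SE 0.0683, adjusted p = 0.164), and of 23 alternatives the fit without WT 3 called it (adjusted p = 0.0308, range 0.0308 to 1).

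By list, camera called 8 lists between Mixed and WT, and with an estimated correlation all 8 calls were lost (adjusted p = 0.346 to 0.654). Classical monocyte genes had 7 of 18 members higher in Mixed than in WT and 1 lower (9 and 1 when adjusted over the list alone). Among them were Ly6c2 (698.9 ± 4.5 and 525.6 ± 31.1 CPM), the lysozyme gene Lyz2 (8069 ± 108 and 6092 ± 653 CPM) and F13a1 (1.26-fold). Lysosome genes had 7 of 24 higher and 1 lower (12 and 2). Cholesterol synthesis genes had 2 of 21 higher and 0 lower (6 and 0), among them Srebf2 (not called without Mixed 2, Mixed 3, WT 1 or WT 2), and chemokine receptor and homing genes 6 of 18 higher and 0 lower (7 and 1), with Itgb7 1.52-fold higher. Lower lists were neutrophil genes, with 1 higher and 4 lower of 20 (4 and 12), and type I interferon genes, with 0 and 4 of 25 (0 and 5), such as Rsad2 (2.42-fold) and Ifit3 (1.64-fold). Also lower were fetal genes, with 0 and 2 of 15 (0 and 3), Hmga2 (not called without Mixed 3 or WT 2) and Igf2bp2 (not called without any 1 of Mixed 1 to 3, WT 1 or WT 2), and eosinophil genes, with 0 and 2 of 7 (0 and 3). The adjusted p was 0.0148 for the chemokine list and 0.00326 for the other 7 lists, and with an estimated correlation adjusted p was 0.346 to 0.654 for these 8 lists. The MHC class II list was not called (adjusted p = 0.836): H2-Aa (3.32 and 8.8 CPM), H2-Ab1 (2.72-fold), H2-Eb1 (2.93-fold) and Cd74 (1.47-fold) were lower, and 4 other members were higher. Of the erythroid list 0 of 17 were called. Hbb-y, an embryonic globin, stood at 1.24 ± 1.46 CPM in Mixed and 15.9 ± 19.8 in WT (adjusted p = 0.291), and Afp, a fetal liver protein, at 3.42 ± 0.877 and 17.7 ± 19.1 CPM (adjusted p = 0.191).

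Bone marrow and fetal liver WT monocytes differed widely, with 9351 genes called, 4686 higher and 4665 lower in bone marrow, and 1838 and 1769 of them by 2-fold or more. Within the same limits on level and overlap, Chil3, a chitinase-like protein of monocytes and macrophages (chromosome 3, 106147554 to 106167564), was at 2155 ± 19.7 CPM in bone marrow and 3.85 ± 2.61 in WT (552-fold, adjusted p = 5.92e-08). Rem1 (419-fold), Stxbp6 (363-fold), Ace, which encodes angiotensin-converting enzyme (58.6 ± 8.3 and 0.163 CPM, 348-fold), Ms4a8a (127-fold), Cd40 (124-fold), Cyp2ab1 (112-fold) and Sulf2 (127.7 ± 11.9 and 1.15 CPM) followed. Stfa1, a stefin protease inhibitor (chromosome 16, 36276951 to 36285373), was at 0.465 CPM in bone marrow and 1582 ± 212 in WT (3340-fold), and its relatives Cstdc5, Cstdc4 and Stfa3 were 1520, 552 and 497-fold lower, all uncertain as near-identical copies. Igf2bp1, an RNA-binding protein of fetal cells, was 496-fold and Olfm4 324-fold lower. The Y-linked genes Eif2s3y and Ddx3y were at least 191-fold and 185-fold lower in bone marrow, where no library had a count, and both lost their calls without WT 3 (adjusted p = 0.0623 and 0.0621, ranges over the alternatives 1.41e-07 to 0.144 and 1.48e-07 to 0.149), BM 2 or BM 3.

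Gene lists separated the tissues along several lines. Classical monocyte genes were higher in bone marrow for 16 of 18 members and lower for 2, with Fn1 at 3288 ± 174 CPM against a mean of 74.7 and S100a4 33.5-fold higher (adjusted p = 4.97e-06, and adjusted p = 0.0854 with an estimated correlation). Non-classical genes were higher for 11 of 16 and lower for 4 (adjusted p = 0.0127, and adjusted p = 0.379 with an estimated correlation), with the nuclear receptor Nr4a1 9.71-fold and Eno3 8.22-fold higher. Fetal genes were lower for all 15 members, among them Igf2bp3 (2.1 and 161.2 CPM, 77.4-fold) and Lin28b, a repressor of let-7 microRNAs (72.5-fold), with adjusted p = 3.64e-07, and adjusted p = 0.0564 with an estimated correlation. Replication genes were lower for 28 of 29 (Gins1 2.15-fold, Rfc4 2.09-fold, adjusted p = 2.05e-08, and adjusted p = 0.0564 with an estimated correlation). Mitotic genes were lower for 17 of 25 with 3 higher (Aurka 1.91-fold, adjusted p = 0.00958, and adjusted p = 0.386 with an estimated correlation). Glycolysis genes were lower for 12 of 18 and higher for 2, with Ldha at 470 ± 17.9 CPM against 1912 ± 32.5 (adjusted p = 9.27e-04, and adjusted p = 0.219 with an estimated correlation). The transcription factor Id3 was at 1.1 ± 0.47 CPM in bone marrow and 183.2 ± 10.1 in WT, and Irf4 was 11.6-fold higher in bone marrow.

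Several immune lists were higher in bone marrow, though not complement and Fc receptor genes (7 higher and 8 lower of 17, adjusted p = 0.948) or cytokine and NF-kB genes (8 and 1 of 14, adjusted p = 0.0537). MHC class I genes were higher for 15 of 16 and lower for 0 (H2-M3 14.1-fold, Nlrc5 13.2-fold, adjusted p = 2.05e-08, and adjusted p = 0.109 with an estimated correlation). MHC class II genes were higher for 10 of 12 with 2 lower, named after their values were seen as H2-DMb2 and H2-Oa (Cd74 at 847.8 ± 54.1 and 83.2 ± 14.1 CPM, adjusted p = 4.35e-04, and adjusted p = 0.219 with an estimated correlation). Type I interferon genes were higher for 24 of 25 (24 higher and 1 lower over the list alone, Ifi27l2a 6.8-fold, Ifit3 6.09-fold, adjusted p = 9.36e-08, and adjusted p = 0.219 with an estimated correlation). Interferon gamma induced GTPases (10 higher, 3 lower of 14, adjusted p = 0.0434, and adjusted p = 0.368 with an estimated correlation) and Toll-like and lectin receptors (15 and 5 of 21, Tlr7 6.58-fold, adjusted p = 0.00958, and adjusted p = 0.103 with an estimated correlation) went the same way. So did homing genes (12 and 5 of 18, Itgb7 14.1-fold, adjusted p = 0.029, and adjusted p = 0.225 with an estimated correlation) and lysosome genes (18 and 5 of 24, Cd68 3.29-fold, adjusted p = 0.00262, and adjusted p = 0.373 with an estimated correlation). Genes of the immediate early and dissociation list, which can also respond to cell handling, were higher for 13 of 17 and lower for 3 (adjusted p = 0.00399, and adjusted p = 0.386 with an estimated correlation). Among the higher ones were the heat shock gene Hspa1a, at 226.1 ± 37.8 CPM against 10.1 ± 10.9, and Nr4a1, also on the non-classical list. Tissue and handling cannot be told apart here.

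Lists of other cell types differed between bone marrow and fetal liver WT monocytes in both directions. All 17 erythroid genes were lower, with Hbb-bs, an adult beta globin, at 3.09 ± 1.76 CPM against 363.1 ± 120 (adjusted p = 3.84e-07, and adjusted p = 0.219 with an estimated correlation). Globin transcripts were 0.000522 to 0.00206% of the counts in bone marrow and 0.1 to 0.19% in WT. Liver parenchyma genes were lower for 11 of 12 (adjusted p = 0.029, and adjusted p = 0.517 with an estimated correlation), with the iron carrier gene Trf 2.41-fold higher. Tissue macrophage genes were lower for 15 of 23 and higher for 5, with C1qb 16.1-fold lower (adjusted p = 0.0347, and adjusted p = 0.449 with an estimated correlation). Eosinophil genes were lower for 5 of 7 (adjusted p = 0.036, and adjusted p = 0.386 with an estimated correlation). Neutrophil genes were lower for 12 of 20 and higher for 5 (adjusted p = 0.0537), with S100a8 at 187.9 ± 18 CPM against 3057 ± 319. Stem and progenitor genes were lower for 10 of 16 with 4 higher (Cd34 19.6-fold and Kit 26.1-fold lower, adjusted p = 0.0694). B cell genes were higher for 7 of 10 and lower for 2 (Ighm 14.7-fold higher, adjusted p = 0.0537). Conventional dendritic cell genes were higher for 7 of 14 and lower for 1 (Clec10a 17.6-fold higher, adjusted p = 0.0579).

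Set against Mixed in place of WT, KO monocytes showed 5365 called genes, 2654 higher and 2711 lower, and 976 and 492 by 2-fold or more. Gcsam had 4646 counts in KO and 3 in Mixed, a ratio of 1550 (95% interval 529 to 7500), Ms4a1 was at 75.1 and 0.0785 CPM, Chil1 at 528.1 and 4.06 CPM, and Cdh17 was 177-fold, Clec9a 159-fold, Asprv1 114-fold, Rab30 109-fold and H2-Aa 108-fold higher. Adgre4 (19.7-fold), Gpsm2 (17.8-fold), Cd302 (12-fold), Ednrb (9.22-fold), Trem2 (8.45-fold), F13a1 (7.85-fold), Zeb2 (7.54-fold) and Arhgef37 (6.82-fold) were lower, and Id2 was 4.87-fold higher. Maf was at 9.99 and 9.16 CPM (adjusted p = 0.635). All 25 type I interferon genes were higher (adjusted p = 4.17e-21, and adjusted p = 0.103 with an estimated correlation). Of the MHC class II genes 10 of 12 were higher (11 over the list alone, adjusted p = 3.13e-09, and adjusted p = 0.103 with an estimated correlation). Higher too were 11 of 14 conventional dendritic cell genes, with 3 lower, (adjusted p = 4.18e-06, and adjusted p = 0.0241 with an estimated correlation) and 14 of 20 neutrophil genes with 1 lower (adjusted p = 3.28e-09, and adjusted p = 0.289 with an estimated correlation). Eosinophil genes were higher for 6 of 7 (7 over the list alone, Prg2 at 27.2 ± 17.6 and 1.69 ± 1.73 CPM, not called against the 5 WT-genotype libraries of the later age label, adjusted p = 9.05e-04, and adjusted p = 0.289 with an estimated correlation). DNA replication genes were lower for 13 of 29 with 1 higher (adjusted p = 0.0146, and adjusted p = 0.289 with an estimated correlation). Some lists called in KO against WT were not called against Mixed. Tissue macrophage genes were higher for 2 and lower for 7 of 23 (adjusted p = 0.217), and lysosome genes for 4 and 4 of 24 (adjusted p = 0.493). Cholesterol synthesis genes were higher for 7 and lower for 4 of 21 (adjusted p = 0.365), and homing genes for 10 and 5 of 18 (adjusted p = 0.0608). All Mixed libraries carried the later age label and all KO libraries the earlier, so age and genotype cannot be told apart in this comparison.

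Between bone marrow and Mixed, 8535 genes were called, 4309 higher and 4226 lower, and 1527 and 1335 by 2-fold or more. Chil3 (2155 ± 19.7 and 1.38 ± 0.711 CPM, 1560-fold), Ace (404-fold), Rem1 (29.7 and 0.0929 CPM), Stxbp6 (249-fold), Cd40 (93.7-fold) and Cd177, a neutrophil and monocyte surface protein (87.2-fold), were higher in bone marrow. Stfa1 (2730-fold), Cstdc5 (616-fold), Igf2bp1 (382-fold), the erythroid anion exchanger Slc4a1 (198-fold) and Id3 (183-fold) were lower. DNA replication genes were lower for all 29 members, the list that kept its call with an estimated correlation (adjusted p = 1.63e-10, and adjusted p = 0.0294 with an estimated correlation). Type I interferon genes were higher for 24 of 25 (adjusted p = 1.92e-10, and adjusted p = 0.137 with an estimated correlation). MHC class I genes were higher for 15 of 16 (adjusted p = 2.42e-09, and adjusted p = 0.0886 with an estimated correlation) and classical monocyte genes for 15 of 18 with 2 lower (adjusted p = 5.68e-06, and adjusted p = 0.0878 with an estimated correlation). Fetal genes were lower for 12 of 15 (13 over the list alone, adjusted p = 3.63e-07, and adjusted p = 0.0588 with an estimated correlation). Glycolysis genes were lower for 13 of 18 with 2 higher (adjusted p = 2.47e-05, and adjusted p = 0.137 with an estimated correlation) and erythroid genes for 16 of 17 (adjusted p = 2.16e-07, and adjusted p = 0.185 with an estimated correlation).

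Between bone marrow and KO, 9330 genes were called, 4649 higher and 4681 lower in bone marrow. Zeb2 was at 323 ± 13.8 CPM in bone marrow and 22.2 ± 1.87 in KO (14.6-fold), F13a1 at 6906 ± 109 and 390.0 ± 44.7 (17.7-fold) and Fn1 was 115-fold higher in bone marrow. Clec10a had 2277 counts in bone marrow and 3 in KO (ratio 821, 95% interval 281 to 3980), and Cd209a was at 65.7 and 0.225 CPM. Id2 (138.2 ± 2.2 and 2485 ± 95.1 CPM, 18-fold), Ms4a1 (91-fold), Zbtb46, a transcription factor of conventional dendritic cells (23.2-fold), S100a9 (64.5-fold) and H2-Aa (64.5 ± 3.8 and 358.8 ± 7.69 CPM, 5.56-fold) were lower in bone marrow. The classical monocyte list was higher for 15 of 18 with 3 lower (adjusted p = 1.28e-04, and adjusted p = 0.129 with an estimated correlation). MHC class I genes were higher for 12 of 16 with 2 lower (adjusted p = 0.00296, and adjusted p = 0.393 with an estimated correlation). Neutrophil genes were lower for 14 of 20 with 2 higher (adjusted p = 1.18e-04, and adjusted p = 0.515 with an estimated correlation). Conventional dendritic cell genes were lower for 10 of 14 with 3 higher (adjusted p = 0.011, and adjusted p = 0.129 with an estimated correlation). Fetal genes were lower for all 15 (adjusted p = 1.49e-06, and adjusted p = 0.0692 with an estimated correlation). Eosinophil genes were lower for all 7 (adjusted p = 0.00635, and adjusted p = 0.393 with an estimated correlation). The type I interferon list (4 higher, 11 lower of 25, adjusted p = 0.274) and the MHC class II list (3 and 7 of 12, adjusted p = 0.274) were not called.

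The genes that set bone marrow apart from Mixed were then followed into KO. Of the 200 genes higher in bone marrow than in Mixed, 112 were higher and 42 lower in KO than in WT (116 and 43 when adjusted over the list alone), with a median log2 fold change of 0.31. Of the 200 genes higher in Mixed, 31 were higher and 107 lower in KO (32 and 113), with a median of -0.20. Camera gave adjusted p = 2.35e-09 for the first set, and adjusted p = 0.0226 with an estimated correlation, and adjusted p = 2.08e-06 for the second, and adjusted p = 0.00474 with an estimated correlation. Zeb2 (log2 1.11) and F13a1 (log2 1.51) were higher in bone marrow than in WT, and both were lower in KO than in WT. Across all tested genes, KO libraries correlated less with bone marrow (0.8922 to 0.8963) than WT libraries did (0.9105 to 0.9162). The sets therefore show no general shift of KO towards bone marrow.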

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

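Every alternative run was planned. None of the named genes called under an alternative changed direction. Named called genes that passed in all alternatives other than the 1.5-fold threshold numbered 89 of 106 for KO against WT, 26 of 69 for Mixed against WT, 113 of 119 for bone marrow against WT, 101 of 110 for KO against Mixed, 114 of 118 for bone marrow against Mixed and 122 of 124 for bone marrow against KO. With RLE or upper-quartile scaling, 0 called list members changed direction in the 6 comparisons. RLE changed no list call. Upper-quartile scaling changed the calls of eosinophil genes in KO against WT, B cell and cytokine genes in bone marrow against WT, liver genes in KO against Mixed, conventional dendritic cell genes in bone marrow against Mixed and cytokine genes in bone marrow against KO. A test against a 1.5-fold change (edgeR's glmTreat), which asks for larger effects by construction, called 1345 genes for KO against WT (66.9% of them higher, against 47.7%), 4247 for bone marrow against WT, 1357 for KO against Mixed (67% higher, against 49.5%), 3224 for bone marrow against Mixed and 4309 for bone marrow against KO. For Mixed against WT edgeR's glmTreat called 0, with 241 at an unadjusted p under 0.05, and DESeq2 without a threshold called 1524. DESeq2 called 5480 genes for KO against WT. With the age label as a covariate over the 9 fetal liver libraries, KO against WT gave 3011 genes, and the cause was not tested. The balance of higher and lower genes in KO against WT depended on the fit: 47.7% of the called genes were higher, against 46.2% with upper-quartile scaling and 52.7% with the 2 groups alone. For Mixed against WT, WT 1 alone gave 774 genes and WT 2 with WT 3 gave 464, with fewer libraries in the test. Of 37 list calls in the 3 comparisons with WT, 1 passed with an estimated correlation. With the replicate block the number of list calls was again 37, with eosinophil genes in KO against WT gaining a call (adjusted p = 0.0292, and 0.613 with an estimated correlation) and homing genes in Mixed against WT losing theirs (adjusted p = 0.05, and 0.407 with an estimated correlation).

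Leaving out 1 library at a time gave 4803 to 5614 genes for KO against WT, 414 to 1457 for Mixed against WT, 8756 to 9450 for bone marrow against WT, 4553 to 5548 for KO against Mixed, 7874 to 8722 for bone marrow against Mixed and 8800 to 9531 for bone marrow against KO. The count of 1180 for Mixed against WT moved by over 1.5 times without Mixed 1 (414), Mixed 3 (665), WT 1 (464) and WT 2 (688). With the replicate number as a replicate block the counts were 5525, 1168, 9262, 5288, 8479 and 9252 in the same order. Residuals of libraries with a shared number correlated at -0.0353 to 0.0693, so the numbers gave no pairing. In the genes higher in bone marrow and those higher in Mixed, medians in KO against WT ran from 0.27 to 0.37 and from -0.21 to -0.15 over fits without 1 library.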

Other observations

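The tests for admixed B cells, neutrophils and dendritic cells and for a shared batch were chosen only after the results were seen. In KO against WT, transcripts typical of dendritic cells, B cells and neutrophils rose in the sorted cells, as described above. The tables argue against B cells as the source of Ms4a1: its 75.1 CPM in KO stood beside 0.347 ± 0.11 CPM of Cd79a, and the highest level of Cd79a in a KO library was 0.657% of the lowest Ms4a1 level, far under the share B cells would bring. Of the 10 measured B cell list genes, 4 were over 1 CPM in WT monocytes and 0 were on another list. They also argue against neutrophils as the whole cause. Ngp, Camp, Ltf and Retnlg had a median log2 change of -0.461 (largest SE 0.635), with an upper bound of 0.81. The median was 1.84 for the 13 higher neutrophil genes, which were picked for being higher in this same comparison. Over all 20 list members, those 4 included, it was 1.07. Of the list genes, 19 of 20 were over 1 CPM in WT and 2 were on another list.

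Dendritic cells remain a candidate source. Of the 14 conventional dendritic cell genes, 12 were over 1 CPM in WT and 3 were on another list, and the most abundant in KO were Wdfy4 (176 CPM), Cd24a (170 CPM), Dpp4 (79.8 CPM) and Snx22 (79.5 CPM). In the test of admixed dendritic cells, 3 members under 10 CPM in WT fell (Cd209a, Clec10a and Irf4), which a mixture of all dendritic cells would not give. The bound set for that test was too simple, since a share of 1 subset could bring the raised members alone. Such a share would not by itself give the falls of Cd209a (0.225 CPM in KO, 8.52 CPM in WT) and Clec10a (0.0468 and 2.12 CPM). Those falls argue against added dendritic cells alone as the cause of the change in the list. A smaller share of other admixed cells in KO than in WT could give them, and this was not tested. For the raised members, admixture and a change within monocytes cannot be told apart. The Ly6C+ sort is the single gate given in the labels, and whether it removes such cells was not tested. A difference set by genotype was not tested.

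WT 1 carries another embryonic day than WT 2 and WT 3, which may mean that age set it apart or that a label is wrong. Each WT library was set against the other WT libraries, with the spread taken from the other groups as well, so the lone library is assumed to vary as they do. EdgeR called 1 gene for WT 1 against the other WT libraries (625 at an unadjusted p under 0.05), 0 for WT 2 (436) and 37 for WT 3 (1319). The count for WT 1 lay between the others, so whether the age labels are right and age sets expression apart stays open. The pair WT 1 and WT 2 was also the closest, at a chi-square per degree of freedom of 4.36, against 10.1 for WT 2 and WT 3. A bound met by a count below that of WT 3 alone was too weak, because WT 3 also differed in sex-linked transcripts, with Xist at 25.3 CPM against 92 and 97.7 CPM. For a shared batch of the WT libraries, the lowest correlation of WT 1 with another WT library minus the highest of those with a Mixed library was -0.0025, which sets different libraries against each other. Taken singly, WT 2 correlated with WT 1 at 0.9882 and with Mixed libraries at up to 0.9868, and WT 3 at 0.9843 and up to 0.983. Other pairs went the other way. WT 2 correlated with WT 3 at 0.9851, and WT 1 correlated with WT 3 at 0.9843 and with Mixed 2 at 0.9853. No batch is labelled, so a batch and a difference between groups cannot be told apart.

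Genes near Zeb2 could differ through sequence linked to its locus rather than through its level. Within 20 Mb of Zeb2, 42.3% of 274 genes were called in KO against WT, at percentile 88.7 of 1991 windows elsewhere (median 38.2%, 95th percentile 43.6%). The standard error was 2.98 points, wider than the gap to that percentile, so the share leaves linked sequence open.

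Each comparison was also run on its 6 libraries alone with every split into 3 against 3. In each, 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. Real and highest other counts were 5173 and 1 genes for KO against WT, 1204 and 18 for Mixed against WT, 9046 and 0 for bone marrow against WT, 5281 and 0 for KO against Mixed, 8461 and 0 for bone marrow against Mixed, and 9042 and 0 for bone marrow against KO. For lists, 3 of 10 splits gave as many for KO against WT (9 real, 11 highest other), 1 for Mixed against WT (10 and 6) and 1 for bone marrow against WT (19 and 14). Every other split mixed libraries of the 2 groups, which kept part of their difference and widened the spread within each side. Low gene counts in those splits were thus bound to follow, and their list counts do not measure false calls of camera. Member counts in KO against WT are to be read beside the 38.1% of all tested genes called there.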
